A study of Mus musculus with 474 samples.

How the data were processed

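Single-cell RNA sequencing (Smart-seq2, a plate method that reads full-length transcripts of one cell per well, with Nextera libraries) was carried out on daughters of mouse haematopoietic stem cells (HSCs). Per the labels, the HSCs came from the bone marrow of male C57BL/6JRj mice aged 12 to 19 weeks, their first division in culture was followed by time-lapse imaging, and the daughters were picked with a micromanipulator. All 474 listed libraries carry the same group in the labels.

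The deposited tables hold counts, that is raw reads per gene and library, with no normalization by the authors. The submitters' processing notes name featureCounts from Subread 1.5.0 and SAMtools. The aligner and the genome build are not given in the sources used here, and the gene identifiers equal those of GENCODE mouse release 21 on GRCm38, which supplied symbols and positions. Each table has 55542 features, of which 92 are ERCC spike-ins (synthetic RNAs added in known amounts) and 55450 are genes, and 27884 genes had a count in at least 1 listed library. The deposited metadata tables hold another kind of value, labels given by the authors to each cell (unit: other): culture experiment, movie, position, colony, sequencing run, plate, well and whether the cell received more ("high") or fewer ("low") lysosomes than its sister. How that label was set is not stated, and no lysosome amounts are given, so a planned test of the size of the asymmetry was not run. A further 171 count columns that belong to no listed sample were not used.

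Sisters were joined by the movie, experiment, position and colony given in the metadata. Divisions with exactly 1 high and 1 low daughter were kept, 203 in number. Both daughters were always on the same plate, and 201 divisions had them in adjacent wells, which the join did not require. Adjacent wells were counted down the columns, so the last well of a column is next to the first of the following column. These 203 divisions hold 406 cells. The other 68 cells, 39 high and 29 low, were in no such division. They are called cells without a sequenced sister here and were left out of comparisons between sisters. The divisions come from 9 culture experiments, 5 in sequencing run 4 with 136 divisions and 4 in run 5 with 67 divisions. The experiment is the replicate. P-values that rest on divisions, cells of a few cultures, are named as such.

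Cells needed at least 50000 counts on genes and 1000 detected genes, which all 474 met. Total counts on genes ranged from 76735 to 2444858 per cell, and reads without molecular identifiers are not independent molecules. Intervals rest on the spread between divisions or experiments, or on the number of divisions for shares.

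For lysosome inheritance, counts were summed per experiment and label and compared with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, experiment as block), with Benjamini-Hochberg adjustment and a threshold of 0.05. A companion fit kept cells apart with the division as block, on genes detected in at least 20% of cells, using a solver written for pairs that was checked against edgeR on 40 genes (largest difference 0.0017 on the log2 scale). Gene lists, 26 in number, were scored per cell as the mean log2(CPM + 1) of their detected genes (CPM, counts relative to the cell's total on genes, on the usual scale), and high minus low was averaged per experiment and tested by an exact sign-flip permutation test over 9 experiments, whose smallest possible p is 0.0039. On the same edgeR fit, limma 3.58.1 gave camera, with a preset correlation of 0.01 and with an estimated correlation, and fry. Library measures were tested in the same exact way. Every permutation and sign-flip test of inheritance was two-sided.

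For kinship, similarity was Pearson's r of log2(CPM + 1) over the 1000 most variable genes, sisters against unrelated cells of the same experiment and plate, tested by the exact sign-flip test over experiments. Per gene, an intraclass correlation between sisters was computed after centring on experiment and plate and tested with an F test over divisions. An intraclass correlation near 1 means that sisters differ little compared with divisions. One near 0 means that sisters differ as much as unrelated cells do. List scores were treated in the same way with a one-sided permutation test over 10000 re-pairings. As cell cycle correction, G1/S and G2/M scores and their squares were regressed out of each gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used here, and matplotlib 3.10.9 for figures.

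Genes are named by a rule. For inheritance these are genes past the threshold, filled up to 20 by the smallest unadjusted p, up to 4 members of each list by unadjusted p, and always Lamp1, Lamp2, Cd63, Ctsd, Myc, Tfrc, Cdkn1c, Procr, Cd48 and Kit. For kinship these are the 25 genes with the highest intraclass correlation and up to 4 members of each list by the same measure. The groups, tests, thresholds, gene lists, cell type markers and this rule were chosen before the data were examined, as were the alternatives, except those on the cell cycle, the track letter, unrelated neighbours as pairs, the spike-in share and the depth behind list scores. The alternatives covered normalization (DESeq2 1.42.0 size factors, scran 1.30.0 factors), the test (DESeq2, limma voom, limma on differences between sisters), filters on genes and cells, the block, the pseudocount, the correlation, the number of genes, each sequencing run alone and each experiment left out in turn. The edgeR fit on sums, the fit over divisions and the intraclass correlation per gene were first tested on simulated data with known changes. The other tests were not.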

Results

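Transcriptomes of single daughters of mouse HSCs were measured after the first division in culture. Divisions with both daughters sequenced, 1 that received more lysosomes (high) and 1 that received fewer (low), numbered from 11 to 38 in each of 9 experiments. Total counts on genes ranged from 76735 to 2444858 per cell, with a median of 846198, and the median number of detected genes was 9867.5. Median totals per experiment ran from 539043 in experiment 77 to 1233874 in experiment 68. Spike-ins took a median of 0.0259% of counts in run 4 and 0.604% in run 5. The series title states that tracking and omics were combined to find regulators of blood stem cell fate, and the deposited labels allow 2 questions: whether daughters with more or fewer lysosomes differ in expression, and how alike sisters are.

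The cells carried the transcripts of HSCs. The transcription factor genes Mecom and Hlf had a count in 100% and 99.8% of cells, with median levels of 1345 and 311.1 CPM. Procr, which encodes the surface receptor EPCR, had a count in 85.4% of cells and Slamf1, the gene of CD150, in 28.7%. The median share of cells with a count was 94.9% over the 8 HSC markers. Among lineage genes, the erythroid marker Car2 had a count in 100% of cells, the granule protease gene Prtn3 in 74.1%, and the platelet genes Pf4 and Itga2b in 69.6% and 60.1%. These were the most often detected of their sets. The 6 erythroid, 6 myeloid and 6 megakaryocyte markers had a count in a median of 7.28%, 3.69% and 33.3% of cells. The 6 lymphoid markers had a count in a median of 2.43% of cells, while in the wider lymphoid list Cd79b had one in 69.4%, Lck in 50.8% and Notch1 in 76.8%. Mpo and Ctsg of myeloid progenitors, C1qa of macrophages and Rag1 of lymphocytes had no count in any cell, nor had Xist, and since Prtn3 was common these zeros in the tables are not read as absence of the transcripts. The myeloid and lymphoid medians above include the zeros of Mpo, Ctsg and Rag1 and may therefore be too low. Of the other myeloid markers besides Prtn3, Elane had a count in 0.42% of cells, Ms4a3 in 6.96% and Csf3r in 50.2%.

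Lysosomes break down and recycle material, and their membrane carries LAMP proteins, so their genes were the first place to look for a difference between high and low daughters. Lamp1 (ENSMUSG00000031447, GRCm38 chromosome 8, 13159161 to 13175338) was at 124.5 ± 33.6 CPM in high and 140.1 ± 38.1 CPM in low daughters (SD over 9 experiments). Its log2 difference, high minus low, was -0.17 ± 0.05 (SE), with a higher value in high daughters in 1 of 9 experiments, and it did not pass (edgeR, adjusted p = 0.999). The Lamp1 difference was -0.12 in run 4 and -0.22 in run 5. Lamp2 stood at 0.07 ± 0.05, the tetraspanin gene Cd63 at 0.03 ± 0.04 and the protease gene Ctsd at 0.06 ± 0.06. Among genes tied to HSC activation or identity, Myc stood at 0.11 ± 0.13, the transferrin receptor gene Tfrc at -0.02 ± 0.10, Procr at -0.15 ± 0.10 and Kit at -0.04 ± 0.06. Over divisions Myc (-0.01 ± 0.20), Procr (0.03 ± 0.18) and Kit (0.01 ± 0.06) had the opposite sign. Cdkn1c at -0.15 ± 0.39 and Cd48 at -1.29 ± 1.23 were measured less precisely, with a count in 37.7% and 4.43% of cells.

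No gene passed the threshold between high and low daughters. Of 15854 genes tested with edgeR on sums, 0 passed and 658 (4.15%) had an unadjusted p under 0.05, of which 310 were lower in high daughters. Over divisions, 0 of 11699 passed and 2.70% had an unadjusted p under 0.05, with 724 genes in limma voom and 668 in limma on differences between sisters. With labels swapped within divisions, the same edgeR fits gave a median of 2.50% over divisions and 4.09% on sums. DESeq2 on the same sums called 3 genes, limma voom over divisions called 1 and a fit over cells without the division block called 2. The 95% interval of the difference lay within 2-fold for 9985 genes on sums and for 8480 (72.5%) over divisions. For the remaining genes a 2-fold difference was not excluded.

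The smallest p belonged to Pip5k1b, which encodes a kinase that makes the membrane lipid PIP2. Pip5k1b (ENSMUSG00000024867, chromosome 19, 24294794 to 24555872) was at 59.3 ± 22.1 CPM in high and 79.5 ± 21.5 CPM in low daughters, a log2 difference of -0.45 ± 0.09 (SE), higher in high daughters in 1 of 9 experiments. Over divisions the Pip5k1b difference was -0.27 ± 0.18. It did not pass with edgeR (adjusted p = 0.999) and was one of the 3 genes of DESeq2 (adjusted p = 0.0355), with differences of -0.47 in run 4 and -0.43 in run 5. The ubiquitin ligase gene Neurl3 stood at -0.26 ± 0.06 (189.9 against 224.9 CPM). On the other side, the endosomal sodium-proton exchanger gene Slc9a8 stood at 0.34 ± 0.08 (105.1 against 83.1 CPM, higher in 8 of 9 experiments), the APC/C inhibitor gene Fbxo5 at 0.36 ± 0.09 and the clock factor gene Npas2 at 1.23 ± 0.30. Sorbs2 (-3.11 ± 0.66) and Zfp658 (2.84 ± 0.69), the other genes called by DESeq2, had a count in 13.3% and 11.8% of cells. The gene called by voom was mt-Rnr2, the mitochondrial 16S rRNA, at 0.26 with weights and 0.04 without, where 3 divisions held 69% of the weight. The 2 genes of the fit without a block were Stpg2 and Reps2, which stood at -1.75 ± 0.43 on sums. Stpg2 and mt-Rnr2 were named after their values were seen.

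Lysosomal gene lists did not separate high from low daughters. Scores of lysosomal hydrolases differed by 0.04 ± 0.12 (SD, n = 9), of lysosome membrane genes by 0.00 ± 0.18, of the proton-pumping vacuolar ATPase by 0.05 ± 0.14, of autophagy and TFEB genes by 0.01 ± 0.13 and of mTORC1 and its lysosomal scaffold by -0.00 ± 0.12. In run 4 the hydrolase difference was -0.01 and in run 5 it was 0.12, so the sign was not shared. The same held for membrane genes (-0.03 in run 4 and 0.04 in run 5) and the vacuolar ATPase (-0.02 and 0.14). Autophagy genes had -0.08 and 0.12, and mTORC1 genes -0.05 and 0.05. HSC identity differed by 0.04 ± 0.12, early activation and multipotent progenitor genes by 0.02 ± 0.14, and the myeloid, megakaryocyte-erythroid and lymphoid lists by 0.02 ± 0.08, 0.01 ± 0.13 and 0.01 ± 0.10. Lists of macrophage and dendritic cells (0.03 ± 0.06), mast cells and basophils (-0.00 ± 0.11) and stroma and endothelium (-0.01 ± 0.08) stood for other cell types. For lysosome membrane, autophagy, mTORC1, HSC identity, megakaryocyte-erythroid, macrophage, mast cell, stroma and iron lists, the mean score and the median log2 difference of the genes had opposite signs, with the largest median at 0.09 for stroma and endothelium.

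By the sign-flip test over experiments, DNA replication genes and interferon genes came nearest to a difference. The G1/S list, genes that copy DNA such as the MCM helicase, was higher in high daughters by 0.19 ± 0.23 (SD, n = 9), in 7 of 9 experiments (exact sign-flip p = 0.043, adjusted p = 0.474), with 0.19 in run 4 and 0.19 in run 5. Over divisions the same list differed by 0.22 (permutation, adjusted p = 0.0338). The interferon response list was higher by 0.11 ± 0.11, also in 7 of 9 experiments (exact p = 0.0234, adjusted p = 0.474), with 0.07 in run 4 and 0.15 in run 5. Its members Isg20, Oasl2 and Oas2, antiviral effectors, stood at 0.54 ± 0.19, 0.44 ± 0.16 and 1.60 ± 0.57, with a count in 64.3%, 81.3% and 18.5% of cells. The immediate early list, fast response genes, was lower by -0.07 ± 0.09 (exact p = 0.0547, adjusted p = 0.474). Its member Btg2, an antiproliferative gene, stood at -1.17 ± 0.35, while Fos (2.93 ± 1.33), Egr1 (1.17 ± 0.44) and Klf2 (0.78 ± 0.47) went the other way. In the mTORC1 list, Rps6kb1 stood at 0.17 ± 0.06 with a higher value in high daughters in 9 of 9 experiments, and Rragb (-0.48 ± 0.21), Mlst8 (-0.35 ± 0.19) and Rheb (-0.12 ± 0.07) were on the other side.

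None of the 26 lists, those above included, differed by more than its SD between experiments. Ribosome biogenesis and MYC targets stood at 0.09 ± 0.25, G2/M genes at 0.07 ± 0.44, asymmetric division and Notch genes at 0.06 ± 0.13, mitochondrially encoded genes at 0.06 ± 0.20, glycolysis at 0.05 ± 0.14, iron and lipid metabolism at 0.03 ± 0.09 and oxidative phosphorylation at 0.02 ± 0.07. Ribosomal proteins stood at -0.03 ± 0.06, quiescence genes at -0.01 ± 0.12 and heat shock genes at -0.01 ± 0.14. Of 26 lists, 0 passed the exact sign-flip permutation test (smallest adjusted p = 0.474) and 0 passed fry (smallest adjusted p = 0.698, and 0.377 for change in either direction). With its preset correlation, camera called ribosomal proteins lower (adjusted p = 0.00207) and interferon (0.00902), ribosome biogenesis (0.0187) and G1/S (0.0488) higher in high daughters, and none of these held (adjusted p = 0.994 with an estimated correlation). In each of the 26 lists, 0 genes passed with p adjusted over the list alone.

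**Figure D1:**
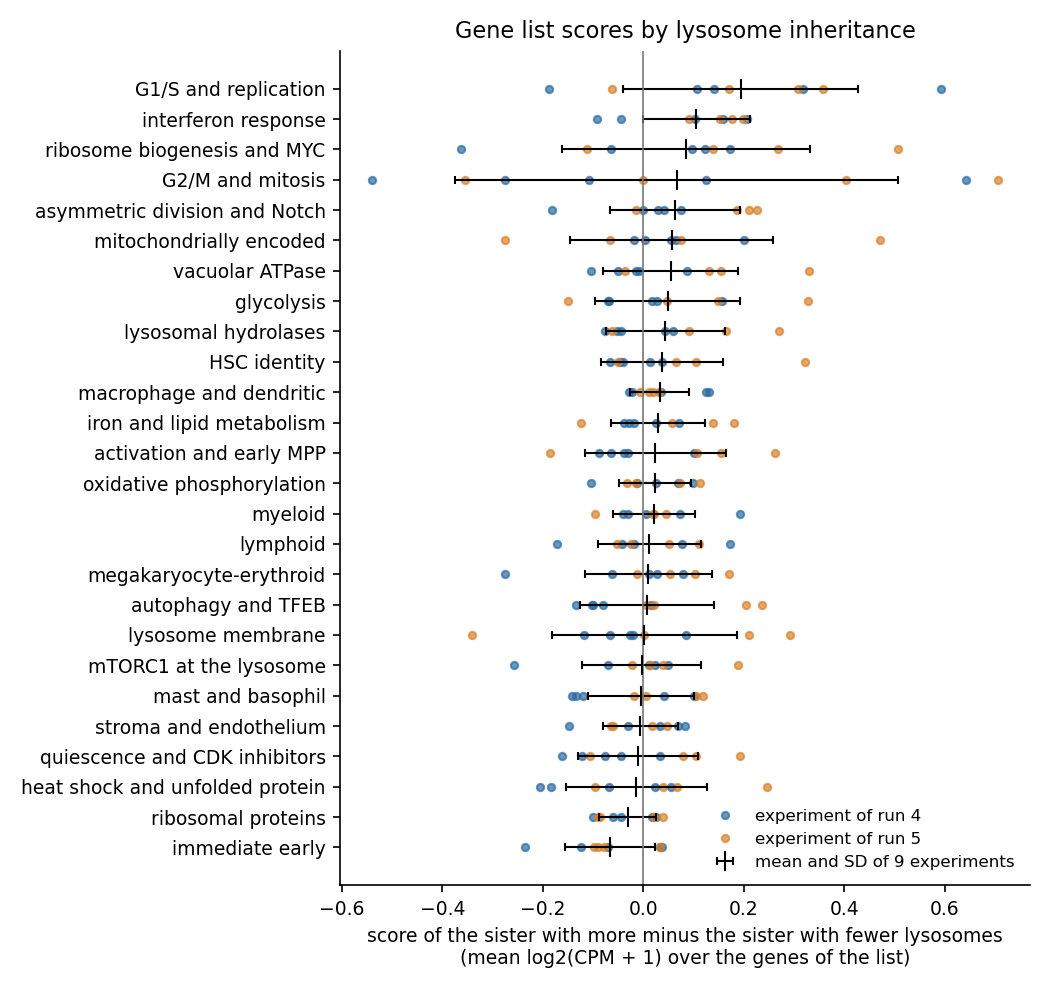
Difference in gene list score between the sister with more and the sister with fewer lysosomes (log2 scale), one point per experiment, with mean and SD of 9 experiments. Points lie on both sides of 0 for each list, and G1/S and interferon have 7 of 9 experiments above 0.

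High and low daughters gave libraries of like size. The log2 total differed by -0.07 ± 0.17 (SD, n = 9; exact sign-flip p = 0.273), detected genes by 67.6, with 5 of 9 experiments higher (exact p = 0.555), the mitochondrial share by 0.10 ± 0.35 percentage points (exact p = 0.566) and log2 counts per spike-in count by 0.08 ± 0.22 (exact p = 0.316). In runs 4 and 5 the difference in log2 total was -0.11 and -0.01, and that in detected genes -50.5 ± 185.4 and 215.2 ± 328.5.

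Sisters resembled each other far more than unrelated cells of the same plate did. Mean Pearson's r was 0.576 between sisters and 0.373 between unrelated cells, a difference of 0.203 ± 0.0211 (SD, n = 9) that was positive in 9 of 9 experiments (exact sign-flip p = 0.0039, the smallest this test can give). It ran from 0.161 in experiment 75 to 0.221 in experiment 69. The difference was 0.204 within run 4 and 0.202 within run 5, where the smallest exact p the test allows is 0.0625 and 0.125.

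**Figure D2:**
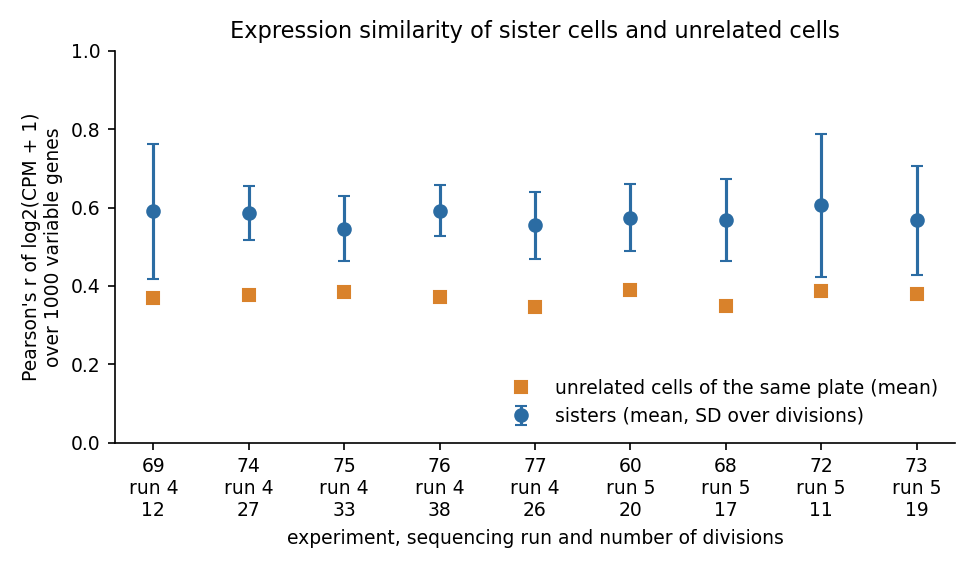
Pearson's r of log2(CPM + 1) over 1000 variable genes for sisters (mean and SD over divisions) and for unrelated cells of the same plate (mean) in each of 9 experiments. Sister means lie between 0.545 and 0.606 and means of unrelated cells between 0.346 and 0.390.

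Genes of mitosis had the highest intraclass correlations between sisters. This measure sets the spread between divisions against that between sisters, and divisions differed widely in these genes. For Plk1 the SD was 3.11 between and 1.39 within divisions (log2 scale), against 0.28 and 0.29 for Pkm of the glycolysis list. The mitotic kinase gene Plk1 (ENSMUSG00000030867, chromosome 7, 122159439 to 122169873) had an intraclass correlation of 0.834 (95% interval 0.787 to 0.872), the highest of all genes tested. The kinetochore gene Nuf2 followed with 0.829, the cyclin gene Ccna2 with 0.828, the kinase genes Aurkb and Ttk with 0.801 and 0.800, and the topoisomerase gene Top2a with 0.757. Of the 25 highest genes, 16 belong to the G2/M list, and replication genes such as Rrm2 (0.696) and Clspn (0.669) came close behind. The G2/M score itself had an intraclass correlation of 0.885, with 45 of 45 genes past the threshold, and the G1/S score 0.753, with 41 of 42. Once cell cycle scores were regressed out, Plk1 fell to 0.0747, Ccna2 to 0.0338 and Top2a to -0.0164, none past the threshold, while Nuf2 at 0.222 and Ttk at 0.249 stayed past it, as did 7 of the 25 highest genes. The G2/M score is itself a mean over a list that holds Plk1, Ccna2 and Top2a, so part of their fall is built in.

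Single genes outside the cell cycle lists were also shared by sisters. Ifi27 (ENSMUSG00000064215, chromosome 12, 103434211 to 103440239), an interferon-inducible mitochondrial protein gene, had an intraclass correlation of 0.806 (0.751 to 0.850) and 0.804 with cell cycle scores regressed out. The galectin gene Lgals1 had 0.780 (0.719 to 0.829) and 0.756 with that correction. Among HSC identity genes, Ifitm1 had 0.627, Ly6a, the gene of Sca-1, 0.590, the clotting factor gene Vwf 0.584 and Procr 0.546 (0.440 to 0.637). These 4 genes remained past the threshold with cell cycle scores regressed out, at 0.589, 0.542, 0.582 and 0.465. The progenitor marker gene Cd34 had 0.638 and the cell cycle kinase gene Cdk6 0.574. Some lineage genes were shared as well, with 0.665 for the Fc receptor chain gene Fcer1g, 0.592 for Cd74 of antigen presentation and 0.559 for the haemoglobin gene Hbb-bt. Others did not pass the threshold, namely Cd79b (-0.057) and Lck (-0.0017) of the lymphoid list and Il4 (-0.0039) and Cpa3 (0.0889) of the mast cell list. Within runs 4 and 5, Ifi27 had 0.853 and 0.693, Vwf 0.574 and 0.606, and Procr 0.489 and 0.651.

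**Figure D3:**
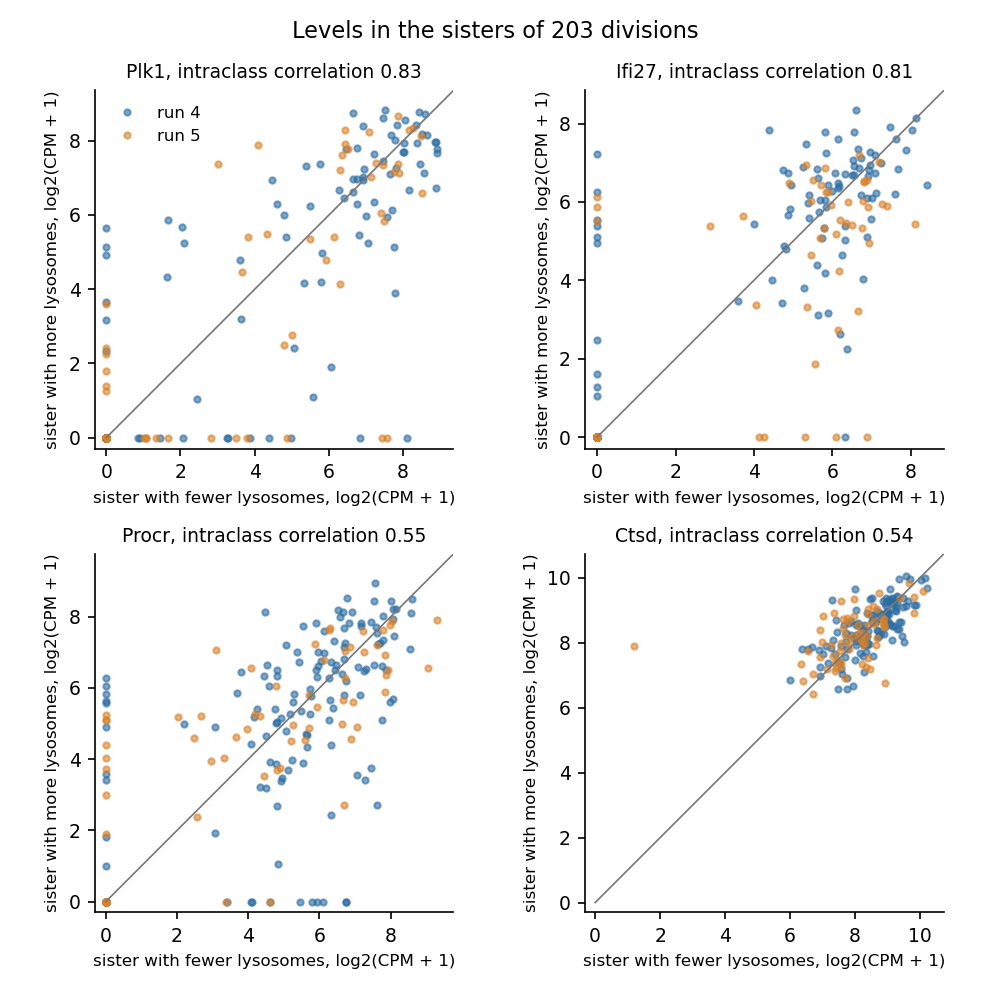
Levels of Plk1, Ifi27, Procr and Ctsd, log2(CPM + 1), in the sister with fewer (x axis) and with more lysosomes (y axis), one point per division, with the line of equality. Intraclass correlations are 0.834, 0.806, 0.546 and 0.541.

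In total 3084 of 11699 genes (26.4%) passed the threshold, with a median intraclass correlation of 0.0858 over all genes tested. Among genes past the threshold 915 reached 0.3, 260 reached 0.5, and 663 were positive in all 9 experiments. Outside the cell cycle lists 2998 of 11612 genes passed, and 1384 passed with cell cycle scores regressed out. These p-values rest on divisions and not on cultures.

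The HSC identity score was shared by sisters, as were the scores of most lineage lists. HSC identity had a score correlation of 0.551 (0.447 to 0.641), with 29 of 40 genes past the threshold and 30 adjusted over the list alone. With cell cycle scores regressed out it was 0.464. The megakaryocyte-erythroid score had 0.530 (11 of 17 genes), the myeloid score 0.492 (8 of 9), the macrophage and dendritic score 0.470 (6 of 6) and the activation score 0.409 (14 of 17). HSC identity had 0.664 in run 4 and 0.403 in run 5. The stroma score had 0.302, the mast cell and basophil score 0.206 and the lymphoid score 0.0616, the single one of 26 that missed the threshold (permutation, adjusted p = 0.156).

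Scores of lysosomal lists were shared by sisters too, as were detected genes (Spearman 0.540) and total counts (0.376). Ctsd (ENSMUSG00000007891, chromosome 7, 142375911 to 142388038), which encodes the protease cathepsin D, had an intraclass correlation of 0.541 (0.435 to 0.633), 0.455 with cell cycle scores regressed out. Ctss had 0.461. The hydrolase score had 0.412 (0.289 to 0.521), with 17 of 43 genes past the threshold and 18 adjusted over the list alone. It was 0.505 with depth and detected genes regressed out, and it had 0.585 in run 4 and 0.254 in run 5. Lysosome membrane genes had 0.214 (12 of 32), the vacuolar ATPase 0.277 (3 of 16), autophagy genes 0.274 (9 of 34) and mTORC1 genes 0.215 (4 of 25). With depth and detected genes regressed out, membrane had 0.343, the vacuolar ATPase 0.350 and autophagy 0.416, while mTORC1 fell to 0.141. With cell cycle scores regressed out, genes past the threshold numbered 9 for hydrolases, 11 for membrane, 0 for the vacuolar ATPase, 3 for autophagy and 2 for mTORC1. The vacuolar ATPase score had 0.422 in run 4 and 0.1655 in run 5. Of all 11699 genes tested, 3084 (26.4%) passed without the cell cycle correction and 1400 with it. The median gene of these 5 lists stood at percentiles 8.94 (mTORC1) to 74.9 (hydrolases) of random lists of like level, against 100 for HSC identity, and at 11.4 (mTORC1) to 95.1 (membrane) with cell cycle scores regressed out. Ribosomal proteins had 0.404 with 52 of 53 genes past the threshold, 0.575 in run 4 and 0.179 in run 5.

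The remaining lists lay between these. Oxidative phosphorylation had 0.458 (28 of 57 genes past the threshold), ribosome biogenesis and MYC targets 0.443 (29 of 42), and iron and lipid metabolism 0.430 (19 of 29), led by the ferritin gene Fth1 at 0.531. With cell cycle scores regressed out, oxidative phosphorylation fell to 0.295 (17 genes) and ribosome biogenesis to 0.284 (20 genes). With depth and detected genes regressed out, glycolysis had 0.147 and asymmetric division and Notch genes 0.143. Interferon genes had 0.284, heat shock genes 0.273 with Hspa8 at 0.632, glycolysis 0.255, asymmetric division and Notch genes 0.239, mitochondrially encoded genes 0.222 (0.406 in run 4 and 0.0524 in run 5), quiescence genes 0.218 and immediate early genes 0.158. With cell cycle scores regressed out, the lymphoid list and the quiescence list (permutation, adjusted p = 0.0548) were the ones outside the cell cycle that did not pass.

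**Figure D4:**
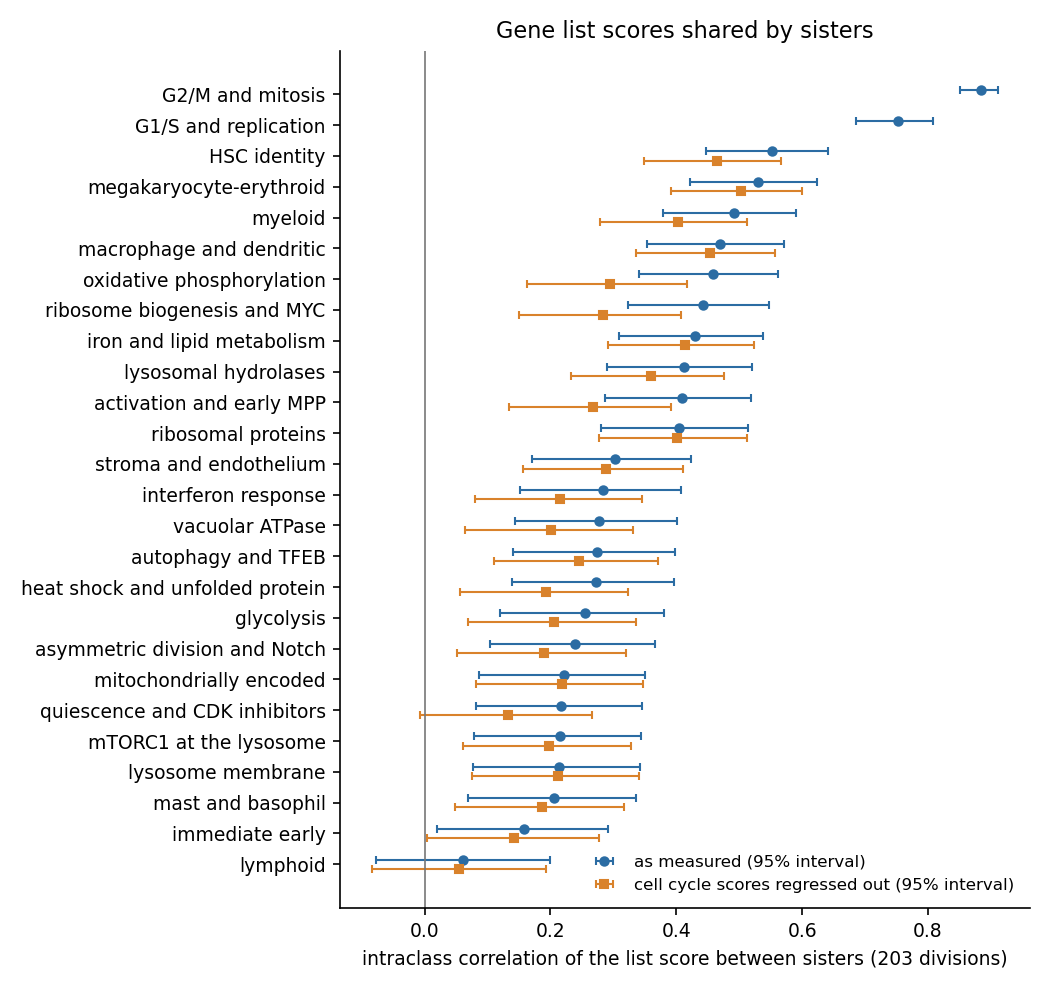
Intraclass correlation of each gene list score between sisters with 95% intervals, as measured and, except for the 2 cell cycle lists, with cell cycle scores regressed out. As measured, values run from 0.0616 for the lymphoid list to 0.885 for G2/M.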

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

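The comparison with unrelated cells in adjacent wells and the count over re-pairings were chosen only after the shared genes had been seen.

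HSC identity scores favoured the high daughter most in experiment 68, as did 12 of the 26 lists in all, and high daughters there had 662.1 more detected genes and 0.46 more log2 counts per spike-in count. There the difference, high minus low, was 0.32, against -0.07 to 0.10 in the other 8 experiments, and the gap to the next experiment made up 0.561 of the whole range. Without experiment 68, where 20 cells also had fewer than 10 Y-linked counts, the mean difference was 0.00237, against 0.04 with it. The mitochondrial share did the same in experiment 69, where high daughters exceeded low ones by 0.94 percentage points, against -0.28 to 0.18 elsewhere, a gap of 0.623 of the range, and without experiment 69 the mean was -0.00787. Over 61 measures, 2 had such a far experiment, and chance alone gives about 1 in 20.

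Spike-in counts, which entered no comparison of genes, took a median of 0.604% of counts in run 5 and 0.0259% in run 4. They were read as a signal in data outside the main measurement and serve below as a technical control.

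The levels of many genes were shared by sisters, 3084 of 11699 tested. Unrelated cells in adjacent wells gave 29 genes, 1.02% of the median of 2854 in as many sister pairs. This argues against processing in neighbouring wells as the main source. The 29 genes, and their pairs' median intraclass correlation of 0.01655, exceeded the highest values in re-pairings, 23 and 0.01396. A small effect of neighbouring wells therefore stays open. Of 100 pairings within experiment and plate, the real one included, 1 gave as many as 3084 genes (highest other 23), so chance can be excluded. Outside the cell cycle lists the count with cell cycle scores regressed out was 46.2% of the one without, so shared cell cycle position could account for part of the pattern and its whole share cannot be told apart, since the regression also removes levels that follow the cycle for any other reason. Technical covariation of sister libraries stays open, because spike-ins of run 5 had a median intraclass correlation of 0.112 (permutation p = 0.0625, and 0.0770 relative to spike-in totals) against 0.0928 in genes of like level, and the 17 abundant ones 0.192 against 0.128, although 0 of 34 spike-ins passed against 8.97% of those genes, and 1736 of 12058 genes in run 5 lay above the highest spike-in (0.266), against a median of 250 in re-pairings. Apart from cell cycle position no biological explanation was tested, since no group in the labels sets some pairs apart from others.

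The absence of genes past the threshold between high and low daughters was set against swapped labels. Of 60 assignments of the labels within divisions, the real one included, 27 gave at least the 658 genes at an unadjusted p under 0.05 found on sums (highest other 894), and 20 gave at least the 2.70% of genes found over divisions (highest other 3.62%), so chance cannot be excluded for these genes. The fit over divisions recovered 61.2% of simulated 2-fold changes. The simulated cells had no levels shared by sisters, so recovery in the real pairs may differ. Smaller or noisier differences could have been missed, and low power cannot be told apart from absence for them.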

How the results depend on the processing

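Settings on the cell cycle, the track letter, unrelated neighbours as pairs, the spike-in share and the depth behind list scores were chosen only after results had been seen. Genes past the threshold by lysosome inheritance numbered 0 on sums in every alternative, each experiment left out included, except DESeq2 (3 genes: Pip5k1b, Sorbs2 and Zfp658), for which the cause was not tested. Over divisions the number was 0 in every alternative except limma voom (1 gene, mt-Rnr2, where 3 divisions held 69% of the weight) and the fit without a division block (2 genes), where the cause was not tested. At an unadjusted p under 0.05 over divisions there were 724 genes with limma voom, 668 with limma on differences and 625 with a 5% detection filter, and on sums without the experiment block 1.69% of genes against 4.15%. For lists the number was 0 except with sign-flips over divisions in place of experiments (1 list, G1/S), a test with more units, and camera at its preset correlation called 4 lists. Signs changed in 10.9% of comparisons of lists and 1.14% of those of named genes. Sister similarity minus that of unrelated cells stayed positive in 9 of 9 experiments under the other correlation, pseudocount, numbers of genes (0.0424 to 0.281), depth-matched and adjacent unrelated cells (0.194 and 0.216), and with the cell cycle left out or regressed out (0.178 and 0.154). It lay from 0.2009 to 0.2084 with each experiment left out, and in run 4 alone (0.2038) and run 5 alone (0.2024) the exact permutation test cannot go below 0.0625 and 0.125 with so few experiments. Genes shared by sisters numbered 2647 to 3154 with each experiment left out and 1201 in run 5 alone, which has fewer divisions. Of list scores, 25 of 26 were shared, and as many with depth and detected genes regressed out. Shared genes numbered 1400 with cell cycle scores regressed out, 1327 with depth regressed out as well, and 29 in unrelated adjacent pairs. With cell cycle scores regressed out, Aurkb (-0.0410), Top2a (-0.0164) and Kif11 (-0.0324) took the opposite sign, as they did with depth regressed out as well (-0.0433, -0.0104 and -0.0335), and all belong to the G2/M list whose score was regressed out. Of 2157 values of named shared genes, 7.23% dropped below the threshold, and 6 rose past it, all of Atp6v0b. Without experiment 68 the difference in detected genes was -6.70 and without experiment 69 that in mitochondrial share was -0.00787, both uncalled and of opposite sign to the values with all experiments. A test against the size of the asymmetry was not run, for want of lysosome amounts. Leaving out the cell filter removed no cell and so tested nothing. Depth limits the rarest genes, for which a 2-fold difference between daughters was not excluded.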

Other observations

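The genes of the next 2 paragraphs, and the relation of HSC identity to ribosomal proteins, were chosen only after their values had been seen.

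Some genes in none of the lists were among the most shared by sisters. Aldh1a1, whose enzyme makes retinoic acid, had an intraclass correlation of 0.715 (95% interval 0.640 to 0.777), and 0.719 with cell cycle scores regressed out, with 0.719 in run 4 and 0.706 in run 5. The inflammatory caspase gene Casp1 had 0.724, with 0.791 in run 4 and 0.556 in run 5. The calcium-binding protein genes S100a6 and S100a4 had 0.706 and 0.629, and the lipid carriers Apoe and Clu, the gene of clusterin, had 0.690 and 0.618. The adhesion receptor gene Adgrl4 had 0.604, the chromatin protein gene Hmga1 had 0.532 and the actin-binding Tmsb10 had 0.517. Apart from Casp1 and Hmga1, with 8, each of these was positive in 9 of 9 experiments.

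The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were split by experiment, although the labels describe all mice as male. In experiment 68, 20 of 49 cells (40.8%) had fewer than 10 counts summed over the 4 genes, with 6 as the highest sum, while the other 29 cells had 87 to 751. The 20 cells were not shallow, with 599717 to 1634562 total counts. Among divisions of that experiment both sisters were below 10 in 6, neither in 10, and in 1 division a sister had 565 counts and the other 0. Elsewhere 1 cell of experiment 60 and 1 of experiment 73 were below 10. Of the X-linked relatives, Eif2s3x had a median of 35.3 CPM in the 20 cells and 30.2 CPM in the other 29, Ddx3x 152.1 and 129.3, Kdm6a 111.2 and 72.98, and Kdm5c 111.7 and 83.7, while Xist had no count in any cell of the series. Without experiment 68 the similarity difference was 0.201, 3154 genes were shared by sisters and 0 genes passed by inheritance.

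Of the cells without a sequenced sister, 39 were high and 29 low, and their median total was 926422 counts, against 833354 in cells with a sister. The track letter Y in the metadata went with the low label in 63.1% of divisions (95% interval 56.02 to 69.70, exact binomial p = 0.000244). With the track letter as a covariate 0 genes passed by inheritance in limma on differences, with 588 at an unadjusted p under 0.05, against 668 without the covariate. The high daughter was in the earlier well in 48.3% of divisions (exact binomial p = 0.674).

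Sisters were closer in pairs with more mitotic transcripts. Across divisions, sister distance over genes outside the cell cycle lists fell with the G2/M score of the pair (Spearman rho -0.554, Pearson's r -0.443, -0.438 without the 2 farthest divisions, permutation p = 1e-05 for both, the smallest possible, adjusted p = 2e-05 among 6 relations), with rho -0.571 in run 4, -0.533 in run 5 and a negative value in 9 of 9 experiments. A candidate explanation is that sisters diverge with time after division as mitotic transcripts decay. Sister distance also fell with the lower depth of the pair, with rho -0.307 (Pearson's r -0.273, -0.298 without 2), -0.138 in run 4 and -0.599 in run 5, though with depth regressed out the first rho was -0.546. Unrelated cells of like G2/M score showed the same fall (rho -0.802). Over all divisions the excess of sister similarity over them did not follow the score (rho -0.0678, permutation p = 0.341). This rho was 0.0130 in run 4 and -0.207 in run 5. The pattern is thus also what mitotic cells being alike in general would give.

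HSC identity and lysosomal hydrolases may vary together between divisions. With cell cycle scores regressed out, the scores had Spearman rho 0.533 and Pearson's r 0.571 across divisions (0.538 without the 2 farthest, permutation p = 1e-05 for both, the smallest possible, adjusted p = 1.92e-05 over 23 lists), with rho 0.473 in run 4, 0.632 in run 5 and a positive value in 9 of 9 experiments. Depth and detection could raise both scores in the same cell. With these regressed out rho was 0.338. Between HSC identity in a cell and hydrolases in its sister it was then 0.151 (permutation, adjusted p = 0.0241), 0.174 in run 4 and 0.105 in run 5. Part of the relation therefore cannot be told apart from depth. The cross-sister value exceeded 98.8% of 1000 random lists of like level (median 0.00999), which argues against a relation that any list would show, but it was not particular to hydrolases, since the vacuolar ATPase (0.162), asymmetric division and Notch (0.151), stroma and endothelium (0.131) and lysosome membrane (0.129) lists passed as well, and activation and early progenitor genes in the opposite direction (-0.180). A predicted fall of ribosome biogenesis with HSC identity did not pass (rho -0.113, permutation p = 0.109, -0.153 in run 4 and 0.00071 in run 5) but did with depth regressed out (rho -0.181, permutation, adjusted p = 0.0260), so it cannot be told apart from none, while ribosomal proteins gave -0.246 across sisters (permutation, adjusted p = 0.00023), -0.222 in run 4 and -0.305 in run 5.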
